A study of Mus musculus with 6 samples.

How the data were processed

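Mouse pancreatic islets were measured by MARS-seq on 6 plates of 384 wells, 3 from sham-operated mice and 3 from mice with a partial pancreatectomy (ppx). The authors deposited UMI counts, 1 table per plate with 1 column per well and no normalisation. Per the submitters' processing notes, reads were aligned with HISAT 0.1.6 to genome build mm10. The counting tool and the gene annotation are not given in the sources used here. The values are whole numbers, every plate has all 384 columns, and the 52542 gene rows stand beside 92 rows of ERCC spike-ins that hold 3 UMIs in total. The series design states 2300 cells from 6 pancreata and a grouping by MetaCell, which was not used here.

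Wells with fewer than 500 UMIs (96) or more than 20% of UMIs from mitochondrial genes (93) were left out, which kept 2115 of 2304 wells. No wells were removed as doublets, since joined cells are the subject of the series. Counts were scaled to the well total and log-transformed. Clusters came from 2000 variable genes, 20 principal components, 15 neighbours and the Leiden method at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). A cluster took the name of a cell type, as in "beta-like", when its foremost marker among the 10 leading genes and the largest number of markers there belonged to that type, with at least 3 of the type's markers seen in at least 10% of its wells. A leading gene had to be seen in at least 25% of the cluster's wells. Gene positions were taken from GENCODE on the GRCm38 assembly.

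A well was called high in insulin (Ins1 and Ins2 summed), somatostatin (Sst) or glucagon (Gcg) when the hormone lay above the midpoint, on the log2 scale of CPM plus 1, between the median of the cell class that makes it and the highest median of the other endocrine classes. The thresholds were 3.27%, 0.731% and 2.33% of a well's UMIs. Intervals of shares are exact Clopper-Pearson intervals at 95%, and the limit for a count of 0 is 3 counts of the total. Both cover counting error only. Shares of wells per plate were compared by exact two-sided permutation of plate labels. The smallest p such an exact permutation test can give is 0.1 for 3 plates against 3 and for 2 against 3. Enrichment of beta-delta wells over beta-alpha wells was the number of wells high in both hormones divided by the product of the numbers of wells high in 1 of them, as a log2 ratio with 0.5 added to each count, tested by exact sign flips over 6 plates (smallest p 0.031). Depth in joined wells was tested in the same way. Markers were counted after thinning each well to 1000 UMIs.

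For gene tests, UMIs were summed over the wells of a class on a plate, so that the plate is the replicate. Plates with at least 10 wells of the class were used, or 5 for joined, somatostatin-only and glucagon-high wells. Sums were tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test, R 4.3.3), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes were taken from the F statistic. The difference of the operation's effect between classes was tested as an interaction with plate as a block, on all plates that had both classes, whatever the number of wells. Joined wells were compared with in silico pairs, each the sum of 1 insulin-only and 1 somatostatin-only well of the same plate held to the same thresholds, with plate as a block. Tomato-positive and tomato-negative plates were compared in beta-like wells with operation as a covariate. The mixed plate was left out there. DESeq2 1.42.0 (Wald test) was the second tool.

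Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry, where at least 5 members were tested. The 16 pathway lists hold beta cell identity, immature or disallowed genes, endoplasmic reticulum stress, proliferation, secretory granules, oxidative phosphorylation, mitochondrially encoded genes, glycolysis, ribosomal proteins, immediate early and dissociation genes, class I antigen presentation with interferon genes, oxidative and metal stress, sterol and lipid synthesis, cell contacts, endocrine receptors, and growth factors. The 13 marker lists hold beta, alpha, delta, pancreatic polypeptide, epsilon, duct, acinar, endothelial, macrophage, lymphocyte, stromal, Schwann and erythroid genes.

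The comparisons, gene lists, thresholds, alternatives and the rule for named genes were set before the data were examined. By that rule the text names, per comparison and direction, up to 12 called genes with the largest changes whose plates do not overlap between groups, the members of each list past the threshold or otherwise those with the smallest p, and always Sox9, Ins1, Ins2, Sst, Gcg, Ppy and Mki67. Where fewer than 10 genes per direction qualified, the next by unadjusted p could be given as values. Of the genes past no threshold, the text gives a few. Some results that the rule would name are not reported here. The count tables hold no row for the tomato reporter. Comparisons in somatostatin-only wells and in glucagon-high wells, and the tests without wells rich in acinar transcripts or in immediate early transcripts, were added after the data were seen.

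The alternatives were other size factors, DESeq2, no filter on low counts, hormone genes left out, replicate number as a block, tomato status as a covariate, no tomato-positive plates, other limits on UMIs, mitochondrial share and doublets, Leiden resolutions of 0.5 and 2, other hormone thresholds, other draws and weights of in silico pairs, and each plate left out in turn. The setting without doublets left out wells marked by the doublet score Scrublet and all wells high in more than 1 hormone. The gene tests were also tested on simulated negative binomial counts, with the depths and dispersions of the real sums. Their mean profile was shared by all plates and classes. In them 100 genes were changed 2-fold and 100 changed 4-fold, all above the median expression. In beta-like wells 80 and 98 of these were called, in alpha-like wells 66 and 99, in somatostatin-only wells 94 and 98, and in joined wells 98 and 97. Unchanged genes called there numbered 8, 5, 9 and 13. The interaction of beta-like with delta-like wells recovered 6 and 45, that with alpha-like wells 37 and 89, and the tomato comparison 20 and 59. Unchanged genes called there numbered 0, 2 and 1. Recovery in the real data can be lower.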

Results

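Islets were taken from male mice 4 weeks after a partial pancreatectomy (ppx), in which part of the pancreas is removed and the rest regenerates, or after a sham operation. Wells were profiled by MARS-seq, a plate-based method that counts unique molecular identifiers (UMIs) at the 3′ end of transcripts. The mice carried a tamoxifen-inducible Cre under the control of Sox9, a gene of duct and progenitor cells, and a tdTomato reporter that marks cells of that lineage. They received tamoxifen (8 mg) from 10 weeks of age and were operated on at 12 weeks. Each operation had 3 plates of 384 wells. Replicate 1 of each operation was sorted as tomato-positive, sham replicate 2 was mixed with 4 rows of positive wells, and sham replicate 3 and ppx replicates 2 and 3 were tomato-negative.

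The sham plates held 1250861, 1458576 and 1378257 UMIs and the ppx plates 1262152, 1472441 and 1508513. After the filters, 355, 353 and 339 wells remained on the sham plates and 356, 362 and 350 on the ppx plates. Their median depth was 2119, 3929 and 3797 UMIs per well on the sham plates and 1954.5, 3702.5 and 3890.5 on the ppx plates. Plates are the replicates, and the labels do not map them to the 6 pancreata, so p-values are not known to cover the spread between mice. The exact tests use the spread between plates. The edgeR tests also draw on the spread of other genes, so a p-value can be far smaller than the plates of a single gene bear out.

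The first comparison asked which islet cell types each operation left. Alpha-like wells, marked by glucagon (Gcg) with Ttr and Irx2, took a smaller share on every ppx plate than on any sham plate, 9.90% ± 2.55 against 19.8% ± 3.23 (SD, n = 3 each). Beta-like wells, marked by Ucn3, Mafa and Slc2a2, made up 55.6% ± 44.4 of ppx and 36.6% ± 27.2 of sham wells. Delta-like wells, marked by Sst and Hhex, made up 17.9% ± 28.3 and 20.9% ± 23.5. The tomato sort separated the plates: delta-like wells took 49.1% ± 2.09 of the positive and 2.11% ± 1.06 of the negative plates (n = 2 and 3), and beta-like wells took 4.92% ± 0.607 and 72.5% ± 15.2.

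The alpha-like difference was -9.92 points (exact permutation p = 0.1, the smallest that n = 3 against 3 allows, BH adjusted p = 0.9 over the shares tested). Within tomato-positive plates it was -7.07 points and within tomato-negative plates -12.5 points. At Leiden resolution 2 it was -7.54 points (exact permutation p = 0.2, n = 3 each), with plates that overlap. On single sham plates the alpha-like share was 16.3% (95% interval 12.6 to 20.6), 20.4% (16.3 to 25) and 22.7% (18.4 to 27.5), and on the ppx plates 9.27% (6.47 to 12.8), 12.7% (9.46 to 16.6) and 7.71% (5.15 to 11.0). The beta-like difference of 19.0 points (exact permutation p = 0.6, n = 3 each) and the delta-like difference of -3.04 points (p = 0.8) were smaller than the spread between plates. On tomato-positive plates they were -0.858 and 2.96 points, and on negative plates 26.1 and -1.71. The beta-like difference was 3.42 points without sham replicate 1, 44.6 without ppx replicate 1, 7.36 without ppx replicate 2 and 5.15 without ppx replicate 3. The delta-like difference was 10.3, -7.55 and -11.9 points without sham replicates 1, 2 and 3, and -19.4, 4.94 and 5.33 without the ppx replicates. Wells high in glucagon alone took 2.89% ± 1.59 of ppx and 11.7% ± 6.50 of sham wells (exact permutation p = 0.2, n = 3 each). A cluster of 303 wells led by Ghrl, Sst and Ins2 had no single cell type and held 156 of the 175 wells high in both insulin and somatostatin. A cluster of 94 wells carried endothelial and stromal markers such as Plvap, Kdr and Sparc at a median of 886 UMIs. At Leiden resolution 2 there was an endothelial cluster of 53 wells. Another of 41 wells carried the stromal markers Rgs5 and Sparc and the duct markers Spp1 and Clu. Macrophage-like wells, marked by Cd74 and C1qb, numbered 18. They were absent from the tomato-positive plates, where 0 of 355 and 0 of 356 wells allow shares of up to 0.845% and 0.843%.

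**Figure D1:**
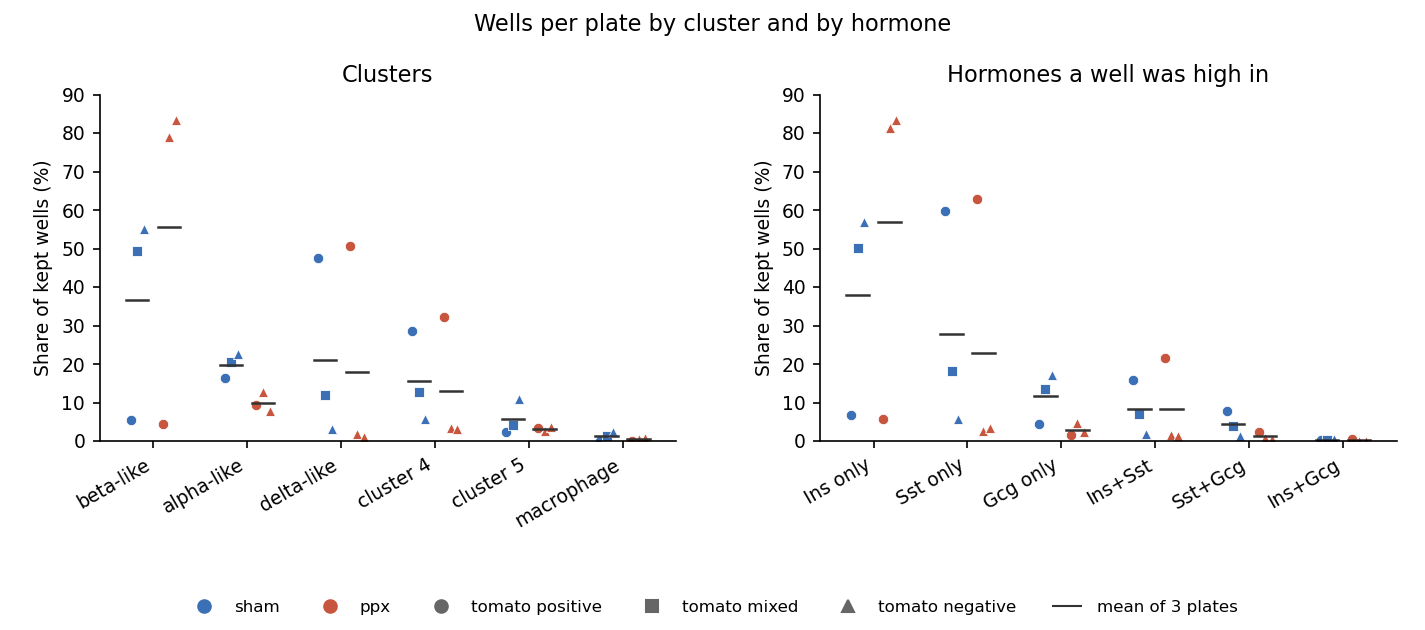
Share of kept wells (%) per plate by cluster (left) and by the hormones a well was high in (right), with sham plates in blue, ppx plates in red, symbols for tomato status and bars for the mean of 3 plates. The 3 ppx plates lie between 7.71% and 12.7% for alpha-like wells, below the 3 sham plates at 16.3% to 22.7%.

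The series title names beta-delta pairs, so wells high in both insulin and somatostatin were taken as candidate pairs. They are called joined wells below, without a test that each holds more than 1 cell. Such wells were common on the tomato-positive plates, where delta-like wells were the most frequent class. Joined wells numbered 56, 25 and 6 on the sham plates and 77, 6 and 5 on the ppx plates. The share was 8.24% ± 11.6 of ppx and 8.21% ± 7.07 of sham wells (difference 0.0295 points, exact permutation p = 1, n = 3 each). The arms differ in tomato status: on the positive plates the share was higher by 5.85 points after ppx (21.6% against 15.8%), and on the negative plates the difference was -0.227. It was 3.81 points without sham replicate 1, -0.534 and -3.19 without sham replicates 2 and 3, and -6.67, 3.32 and 3.43 without ppx replicates 1, 2 and 3. By tomato status it was 18.7% ± 4.14 of the positive and 1.62% ± 0.174 of the negative plates (exact permutation p = 0.1, n = 2 and 3). With the hormone thresholds at 0.25 of the class median, 94 wells in place of 175 were high in both, and the share was 7.32% and 8.15% on the positive plates, while the negative plates kept 6, 6 and 5 wells.

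Among insulin-high wells that were not glucagon-high, 70% and 79.4% on the tomato-positive plates (sham and ppx) were also somatostatin-high, 12.4% on the mixed plate, and 3.02%, 2% and 1.68% on the negative plates. With thresholds at 0.25 of the class median, a setting added after the data were seen, the positive plates stood at 31.7% and 30.2%. The positive and negative plates differed by 72.5 points (exact permutation p = 0.1, n = 2 and 3). Glucagon-high wells that were not insulin-high followed the same sort, at 63.6% and 57.1% on the positive plates against 6.45%, 15% and 20% on the negative ones (difference 46.6 points, exact permutation p = 0.1, n = 2 and 3). At 0.25 of the class median they stood at 40.5% and 28.6% against 6.45%, 15% and 10%. Wells high in insulin and glucagon numbered 6, wells high in somatostatin and glucagon 59, and wells high in all of these hormones 8. Wells high in insulin and somatostatin held 1.24-fold the median UMIs of insulin-only wells, higher on 6 of 6 plates (exact sign-flip p = 0.031, the smallest possible). They held 3.14-fold those of somatostatin-only wells on 6 of 6 plates (exact p = 0.031) and 0.884-fold the sum of both (exact p = 0.09375, lower on 5 of 6 plates).

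Insulin-only wells had a median of 1457 and 1491 CPM Sst on the tomato-positive plates and 187 to 299 CPM on the negative plates, and free RNA was not separated from their own expression. Joined wells of the positive plates stood at 18575 and 18451 CPM, and somatostatin-only wells at 76982 and 77702 CPM. After thinning to 1000 UMIs, 86.2% of joined wells had a UMI of a non-hormone beta marker together with one of a non-hormone delta marker, against 40.6% of insulin-only and 79.9% of somatostatin-only wells. Median depths before thinning were 6091, 4250.5 and 1582.5 UMIs. The shares pool all plates, so kind of well and plate are not separated. The tomato-positive plates held 56 and 77 of the 175 joined wells but 24 and 20 of the 1000 insulin-only wells. Relative to the single wells on a plate, beta-delta wells were more frequent than beta-alpha wells by a mean log2 ratio of 2.59 ± 1.67 (SD, n = 6, above 0 on 5 of 6 plates, exact sign-flip p = 0.0625). Delta-alpha wells exceeded beta-alpha wells by 3.83 ± 3.56 (above 0 on 5 of 6 plates, exact p = 0.09375, n = 6). Beta-delta against delta-alpha wells gave -1.24 ± 2.08 (above 0 on 2 of 6 plates, exact p = 0.25, n = 6).

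**Figure D2:**
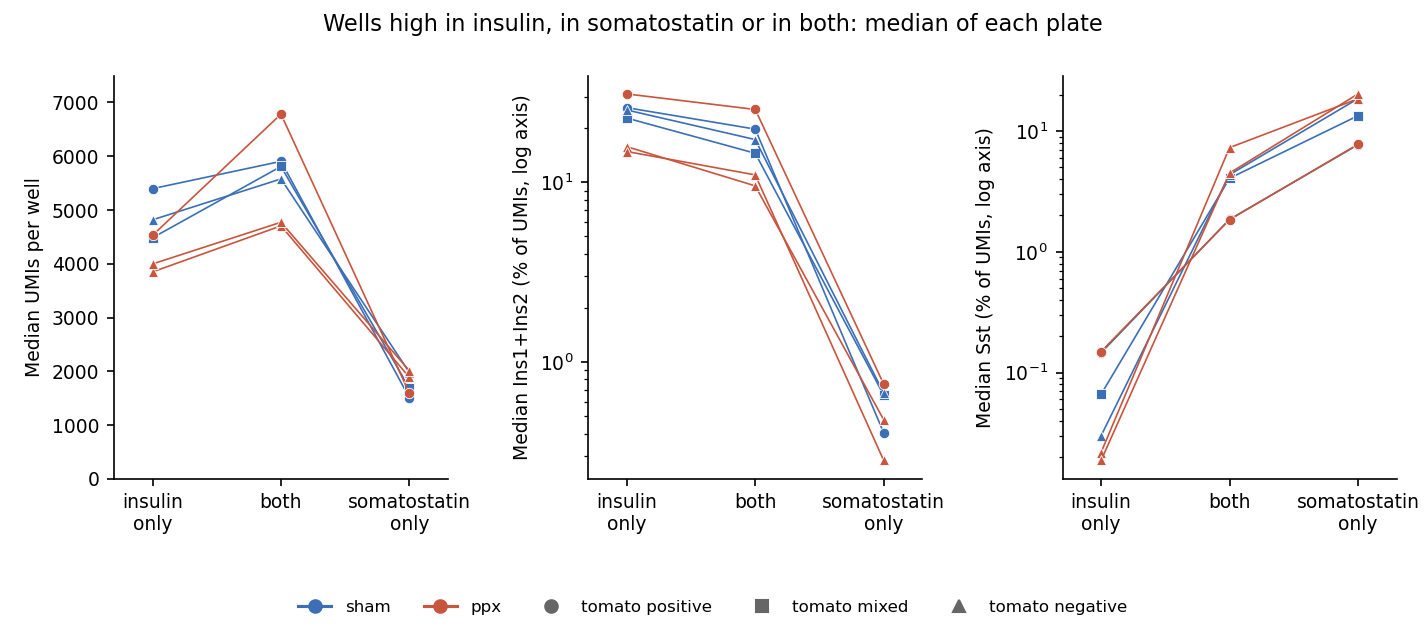
Median UMIs per well, median insulin (% of UMIs, log axis) and median somatostatin (% of UMIs, log axis) in wells high in insulin only, in both hormones and in somatostatin only, 1 line per plate, with sham in blue and ppx in red. Joined wells lie above insulin-only wells in UMIs on 6 of 6 plates, and on the tomato-positive plates their somatostatin is 1.86% and 1.85% of UMIs.

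Joined wells were also compared with sums of separate wells, to see what they express beyond such a sum. Ins1, Ins2, Sst, Gcg and Ppy did not pass (adjusted p = 0.998 for each), and Sox9 and Mki67 were below the count filter. Of 1024 genes, only Gc, the vitamin D-binding protein, differed, lower in joined wells by a log2 fold change of -1.11 ± 0.21 (SE, n = 6 plates, adjusted p = 0.0032). At an unadjusted p under 0.05 there were 35 genes, and DESeq2 also called 1. Pdyn, the opioid precursor prodynorphin, stood at 0.68 ± 0.26 and the glucose-6-phosphatase G6pc2 at -0.35 ± 0.12, and neither passed (adjusted p = 0.998). The Gc call was lost without sham replicate 1, sham replicate 2 or ppx replicate 1 and in 3 of 5 other draws of in silico pairs, each with 0 genes.

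In beta-like wells the question was what 4 weeks of regeneration changed. Several chaperone genes of the endoplasmic reticulum were higher on the ppx plates, 8 of 24 members of a list that did not pass as a set with an estimated correlation. Sdf2l1, a partner of the chaperone BiP, rose by a log2 fold change of 1.58 ± 0.19 (SE, n = 3 plates per operation, adjusted p = 1.1e-07), Pdia4 by 1.33 ± 0.25 and Hspa5, which encodes BiP, by 0.81 ± 0.12. Hspa5 went from 1725 ± 99.5 CPM on sham to 3002 ± 192 CPM on ppx plates. Ins1 (-0.21 ± 0.13, adjusted p = 0.635), Ins2 (-0.33 ± 0.29, adjusted p = 0.792), Sst (1.04 ± 0.42, adjusted p = 0.365) and Ppy (0.66 ± 0.22, adjusted p = 0.198) did not pass, and Sox9 and Mki67 were below the count filter. Gcg fell by 1.72 on the log2 scale in edgeR (SE 0.23, adjusted p = 1.3e-06), beside the smaller alpha-like share of the same plates. It did not pass in DESeq2 (-1.53, Wald test adjusted p = 0.82). Its mean was 2989 ± 771 CPM on sham and 1044 ± 723 CPM on ppx plates.

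Of 8117 genes, 34 rose and 15 fell, and 804 had an unadjusted p under 0.05. The plates of both operations did not overlap for 36 of the 49 genes and for 13.6% of all tested genes, where chance gives 10%. In the list of endoplasmic reticulum stress genes, 8 of 24 rose and 16 did not pass. Adjusted over the list alone, 14 rose and 2 fell. The 8 past the threshold over all genes were Sdf2l1, Pdia4, Hspa5, Creld2 (1.03 ± 0.15), Hyou1 (0.85 ± 0.18), Hsp90b1 (0.72 ± 0.16), Dnajc3 (0.63 ± 0.13) and Manf (0.62 ± 0.13), which encode chaperones, a co-chaperone and secreted stress factors. The list was higher as a set (20 of 24 members positive, median 0.43, camera adjusted p = 1.8e-19). The adjusted p was 0.112 with an estimated correlation (unadjusted p = 0.0057) and 0.0332 with fry. Outside the list, Derl3, a component of degradation from the endoplasmic reticulum, rose by 2.23 ± 0.33 (adjusted p = 1.3e-05) and Fkbp11, a prolyl isomerase of the secretory pathway, by 1.04 ± 0.15.

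**Figure D3:**
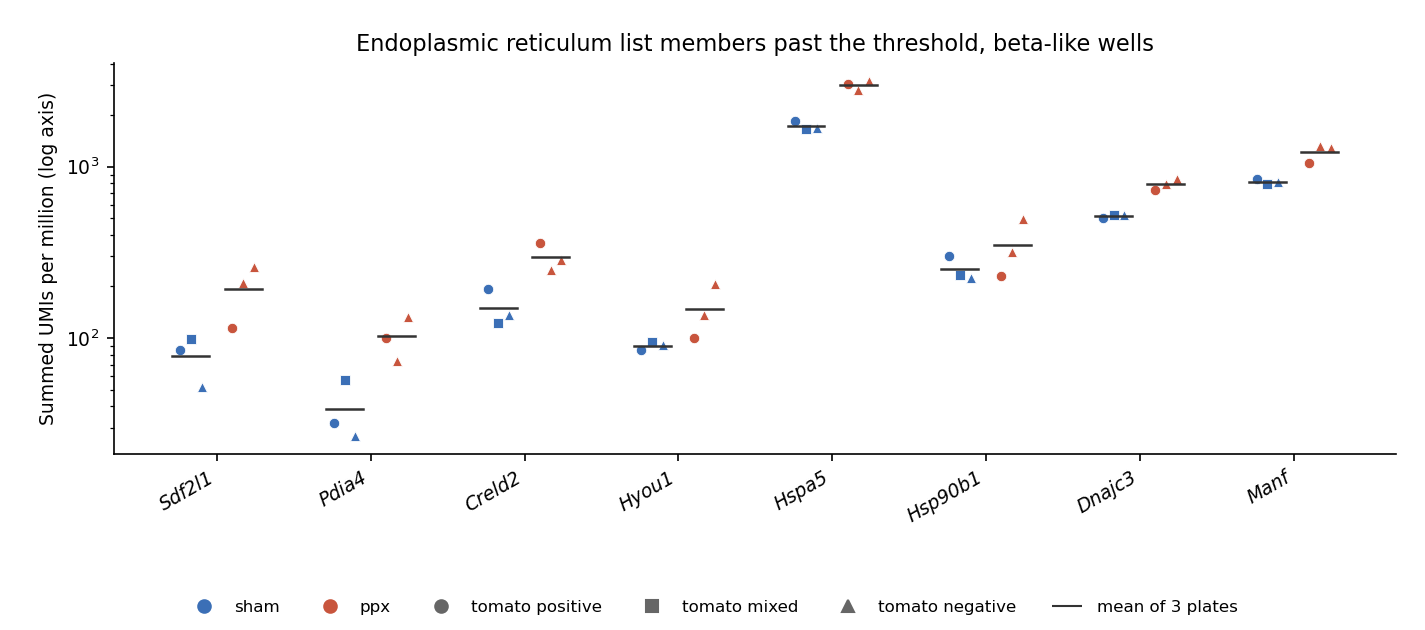
Summed CPM (log axis) in beta-like wells, 1 point per plate, for the 8 members of the endoplasmic reticulum list past the threshold, with sham in blue, ppx in red and bars for the mean of 3 plates. Hspa5 stands between 1660 and 1840 on the sham plates and between 2794 and 3174 on the ppx plates.

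Genes outside that list changed as well. Aldh1a3, a retinaldehyde dehydrogenase used as a marker of dedifferentiating beta cells, rose by 1.5 ± 0.36 (adjusted p = 0.0234) and Serpina7, a thyroxine-binding protein, by 1.19 ± 0.30 (adjusted p = 0.0407). They were the 2 of 5 tested members of the immature or disallowed list that rose (camera adjusted p = 0.0558). Adjusted over the list alone, 2 rose and 1 fell. Also higher were Gc (1.29 ± 0.15), Vgf, a granule peptide precursor (1.19 ± 0.30), Dapl1 (1.04 ± 0.15), the NF-κB inhibitor Nfkbia (0.91 ± 0.15), the splicing factor Hnrnpl (0.90 ± 0.21) and the ATP synthase gene Atp5g1 (0.77 ± 0.19). Lower were the activity-regulated Arc (-1.85 ± 0.47), Gad1, which makes GABA (-1.24 ± 0.18), Lyve1 (-1.23 ± 0.27), Sgsm1 (-1.18 ± 0.26), the motor Myo10 (-0.88 ± 0.22), the exocytosis gene Rims3 (-0.82 ± 0.20), the cation channel Trpm5 (-0.81 ± 0.17), Camk2n1 (-0.67 ± 0.14) and Rap1gap2 (-0.61 ± 0.15). The pseudogene Gm21658 also fell, by 1.79, with plates that overlap.

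Other lists had fewer called members. The immediate early list had 0 of 22 members called by edgeR (6 rose adjusted over the list alone), with 19 positive and a camera adjusted p of 2.3e-06. Its leading members Hspa1a (0.52 ± 0.14, adjusted p = 0.0758) and Hspa1b (0.45 ± 0.14, adjusted p = 0.175) are heat shock genes. Of 29 oxidative phosphorylation genes only Atp5g1 rose (3 adjusted over the list alone), with 26 positive and a camera adjusted p of 3.5e-06. All 6 tested proliferation genes were positive and 0 passed (1 adjusted over the list alone, camera adjusted p = 0.00209), with Tubb5 at 0.67 ± 0.21 and Hmgb2 at 1.29 ± 0.53. Beta cell identity genes were lower as a set (5 of 24 positive, median -0.18, camera adjusted p = 0.0034), with Trpm5 the only member past the threshold over all genes or adjusted over the list alone. Of 20 secretory granule genes Vgf rose (2 adjusted over the list alone, camera adjusted p = 0.0194). With an estimated correlation none of these lists passed: adjusted p = 0.112 for the immediate early, oxidative phosphorylation and proliferation lists, 0.428 for beta cell identity and 0.397 for secretory granules.

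The remaining lists did not pass. Camera adjusted p was 0.0558 for ribosomal proteins, 0.0840 for beta markers, 0.144 for cell contacts, 0.219 for duct markers, 0.481 for glycolysis, 0.512 for class I antigen presentation, 0.548 for sterol synthesis, 0.680 for oxidative stress, 0.717 for endocrine receptors and for growth factors, and 0.829 for mitochondrially encoded genes. For delta markers (adjusted p = 0.680) the median was 0.30 and the mean 0.13 while the test pointed down. For alpha markers (adjusted p = 0.930), where Gc rose and Gcg fell, the median was 0.04 and the mean -0.06. The other 9 lists, the pancreatic polypeptide, epsilon, acinar, endothelial, macrophage, lymphocyte, stromal, Schwann and erythroid markers, had fewer than 5 tested members. DESeq2 called 13 genes, 5 of them in the endoplasmic reticulum list, and the count fell to 24 without sham replicate 2, 21 without sham replicate 3, 29 without ppx replicate 2 and 28 without ppx replicate 3, with 4, 3, 6 and 3 members of that list. Ins2 passed in 5 alternatives, with -1.80 without ppx replicate 1 and -1.79 without both tomato-positive plates (adjusted p = 1.0e-04). Sst passed as a rise in 3, with 1.62 and 1.70 without ppx replicates 2 and 3. Without doublets Sst passed as a fall (-0.98, edgeR adjusted p = 0.0273), but that setting drops wells high in both hormones and so selects on Sst itself. Ppy passed in 3, with 1.09 without ppx replicate 3.

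In alpha-like wells, a class that also held wells rich in pancreatic polypeptide, Ppy and Pyy were higher on the ppx plates, and most tested alpha markers had lower values. Gcg (-0.58 ± 0.28, adjusted p = 0.671), Sst (-0.27 ± 0.28, adjusted p = 0.91), Ins1 (-0.25 ± 0.28, adjusted p = 0.91) and Ins2 (-0.16 ± 0.40, adjusted p = 0.972) did not pass, though Ins2 did without ppx replicate 1 (-1.29, adjusted p = 0.0193), and Sox9 and Mki67 were below the count filter. Ppy, which encodes pancreatic polypeptide, rose by a log2 fold change of 1.71 ± 0.29 (SE, n = 3 plates per operation, adjusted p = 0.00206) and Pyy, which encodes peptide YY, by 1.42 ± 0.27 (adjusted p = 0.00716). Gfra3, a neurotrophic factor receptor, fell by 2.73 (SE 0.51, adjusted p = 0.00619). The mix of wells in the class differed too: 49 of 58, 62 of 72 and 64 of 77 wells were glucagon-high on the sham plates and 17 of 33, 20 of 46 and 10 of 27 on the ppx plates.

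Of 3344 genes, 7 rose and 8 fell, and 244 had an unadjusted p under 0.05. The plates of both operations did not overlap for 14 of the 15 genes and for 12.4% of all tested genes, where chance gives 10%. The rest of the genes that rose were E130111B04Rik, a noncoding RNA near Ppy (3.36 ± 0.51, the gene whose plates overlap), the tetraspanin Tspan8 (1.56 ± 0.23), the transcription factors Klf2 (1.38 ± 0.32) and Klf6 (1.17 ± 0.23), and the heat shock gene Hspa1a (1.07 ± 0.21). Also lower were the complement component C8b (-1.31 ± 0.29), the ribonuclease Rnase4 (-1.30 ± 0.21), the complement inhibitor Serping1 (-1.08 ± 0.25), Rpl34 (-1.0 ± 0.22), Tmsb15b2 (-0.89 ± 0.19) and the zinc transporter Slc30a8 (-0.83 ± 0.19). Fev, a transcription factor of endocrine cells, stood at -1.49 ± 0.39 and did not pass (adjusted p = 0.111).

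Of the endoplasmic reticulum list, 0 of 18 members were called by edgeR (4 rose adjusted over the list alone), with 17 positive, a median of 0.31 and a camera adjusted p of 1.7e-07. Hspa5 stood at 0.58 ± 0.16 (adjusted p = 0.141) and Hsp90b1 at 0.77 ± 0.22 (adjusted p = 0.148). In the immediate early list Klf2, Klf6 and Hspa1a rose (5 of 21 adjusted over the list alone), with 18 positive and a camera adjusted p of 1.5e-06. Both lists held with an estimated correlation (adjusted p = 0.041 each). Duct markers were higher as a set with 1 of 7 called, Tspan8 (4 adjusted over the list alone, camera adjusted p = 2.1e-05), and alpha markers lower with 1 of 14 called (3 adjusted over the list alone, 4 positive, camera adjusted p = 6.8e-05). Their adjusted p was 0.271 and 0.364 with an estimated correlation. The other 14 of 18 lists had camera adjusted p from 0.0664 to 0.997.

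DESeq2 called 13 genes, 9 of them among the 15, and the count was 24 without sham replicate 1, 26 without ppx replicate 1, 6 without ppx replicate 2 and 7 without ppx replicate 3. In glucagon-high wells alone edgeR called 0 of 2325 genes, with 131 at an unadjusted p under 0.05 and Ppy at 1.39 ± 0.37, Pyy at 1.11 ± 0.29, and Gfra3 at -2.02 ± 0.54.

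**Figure D4:**
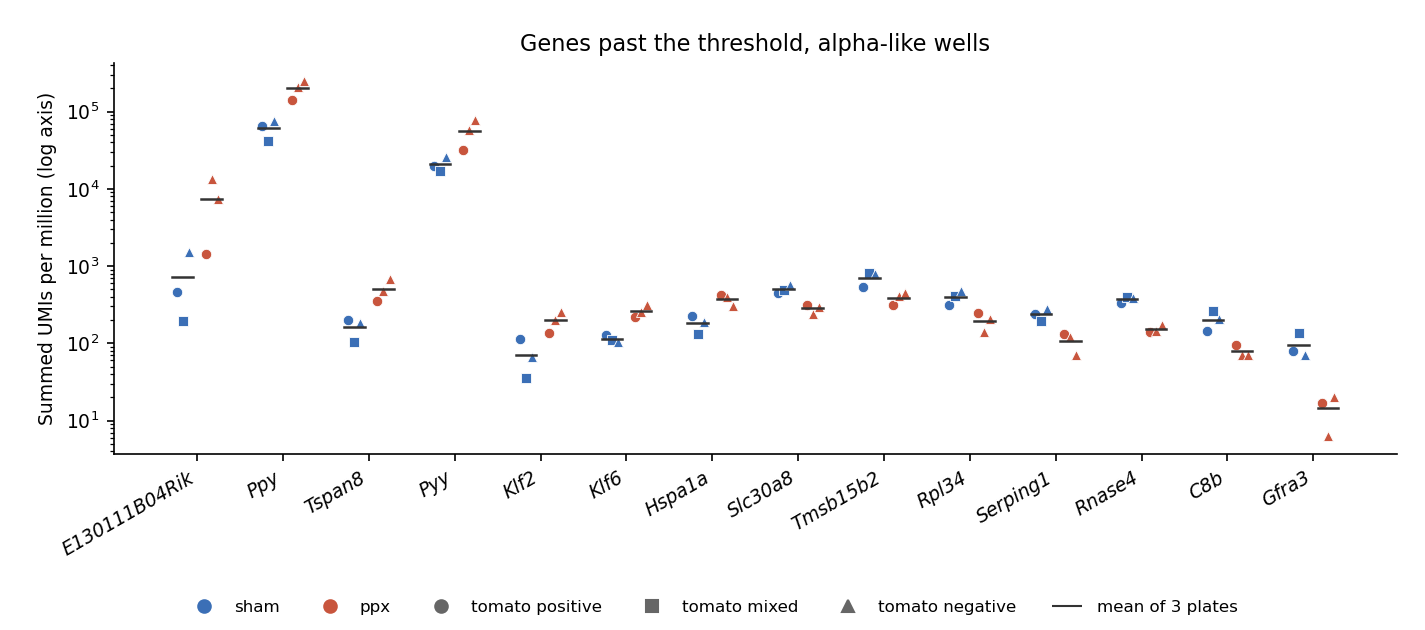
Summed CPM (log axis) in alpha-like wells, 1 point per plate, for 14 of the 15 genes past the threshold, with sham in blue, ppx in red and bars for the mean of 3 plates. Ppy stands between 42182 and 74613 on the sham plates and between 141054 and 251308 on the ppx plates.

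Delta-like wells reached 10 wells on 1 ppx plate (180 wells, against 7 and 4 on the others), so that wells high in somatostatin alone were tested instead. Of these 540 wells, 20 had at least 10% of UMIs in Ppy, and their part in the calls was not tested. The somatostatin-only wells numbered 212, 64 and 19 on the sham plates and 224, 9 and 12 on the ppx plates. They were tested at the lower minimum of 5 wells. In these wells the noncoding RNA E130111B04Rik rose by a log2 fold change of 3.18 ± 0.45 (SE, n = 3 plates per operation, higher on 3 of 3 ppx plates than on any sham plate, adjusted p = 8.9e-05). Ppy stood at 1.11 ± 0.33 (adjusted p = 0.371) and Gcg at -1.03 ± 0.38 (adjusted p = 0.722). Ppy passed in 4 alternatives and Gcg in 3, each also without ppx replicate 2 (1.32 and -1.24). Ins1, Ins2 and Sst did not pass (adjusted p = 1.0 for each), and Sox9 and Mki67 were below the count filter. It was the only call among 923 genes in edgeR and in DESeq2, with 40 genes at an unadjusted p under 0.05. The number called was 9 without ppx replicate 2, 2 without sham replicate 2 and 2 without ppx replicate 3. Delta-like wells from other clusterings gave 1 gene at resolution 0.5, where the cluster takes in most joined wells (Gcg at -1.72, adjusted p = 0.03, 2304 genes), and 1 at resolution 2 (Ghrl at 2.44, with UMIs on the tomato-positive plates only, 2200 genes, 3 sham and 2 ppx plates). DESeq2 called 0 genes at either resolution, with 92 and 72 at an unadjusted p under 0.05 in edgeR.

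Whether an effect of the operation differed between classes was tested directly. Against alpha-like wells, the effect in beta-like wells was higher for the transthyretin gene Ttr (difference 1.24 ± 0.21 on the log2 scale, adjusted p = 4.7e-04), Gc (1.11 ± 0.21) and Rnase4 (1.10 ± 0.23), which alpha cells express. In alpha-like and beta-like wells in turn, Rnase4 stood at -1.30 and -0.17, Ttr at -0.86 and 0.32, and Gc at 0.28 and 1.29. Only Rnase4 in alpha-like and Gc in beta-like wells passed there. The part of the smaller number of glucagon-high wells in the alpha-like class of ppx plates was not tested. In all 4 genes were higher and 4 lower of 5188. Gcg at -1.21 ± 0.30 (adjusted p = 0.0612) and Ppy at -1.20 ± 0.35 (adjusted p = 0.248) did not pass, nor did Ins1, Ins2 or Sst. Gcg passed in 4 alternatives and Ppy in 2. Without ppx replicate 1 both Gcg (-1.64) and Ppy (-1.98) passed, and Gcg also without sham replicate 2 (-1.27). Against delta-like wells, which were few on the tomato-negative plates, the effect was higher for Gc and for the elastase Cela1 among 3989 genes, and none of Ins1, Ins2, Sst, Gcg and Ppy passed (adjusted p = 0.999 each). Of the 424 Cela1 UMIs in beta-like wells of ppx replicate 3, 415 came from 1 well rich in acinar transcripts. The 2 calls against delta-like wells became 0 without sham replicate 1 or sham replicate 2, and 1 without sham replicate 3 or ppx replicate 3, and the 8 against alpha-like wells became 4 without sham replicate 3 and 5 without ppx replicate 2.

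The tomato sort marks the Sox9 lineage, and beta-like wells of positive and negative plates were compared to see how marked beta-like wells differ. Hormones of other islet cells were higher in the beta-like wells of the positive plates, on which delta-like wells were the most frequent class. Sst rose by a log2 fold change of 2.87 ± 0.14 (SE, n = 2 and 3 plates, adjusted p = 4.6e-87), Ppy by 1.14 ± 0.14 and Gcg by 0.97 ± 0.15. Ins2 rose by 1.67 ± 0.20 while Ins1 did not pass (adjusted p = 0.989), and Sox9 and Mki67 were below the count filter. The Ins2 difference came from the ppx plates, with 19.2% of UMIs on the positive and 4.73% and 2.20% on the negative plates, against 11.8% and 10.5% on the sham plates. Ghrl, which encodes ghrelin, had 8 and 24 UMIs in the 19 and 16 beta-like wells of the positive plates and 0 in those of the negative plates. Also higher were the retinol carrier Rbp4 (3.12 ± 0.47), Pyy (1.41 ± 0.17) and the pseudogene Gm5844 (4.58 ± 1.10). Lower were the glutamine synthetase gene Glul (-1.26 ± 0.28), the tetraspanin Cd63 (-1.13 ± 0.22), Gfpt1 of hexosamine synthesis (-1.03 ± 0.24) and Spc25 (-0.99 ± 0.24). Of 8758 genes, 9 rose and 6 fell. Plates did not overlap for 10 of these 15 and for 33.9% of all tested genes, where chance gives 20%. DESeq2 called 3 genes, and without sham replicate 3 or ppx replicate 3 edgeR called 9 and 5. Without sham replicate 1 or ppx replicate 1 a single positive plate is left, so those fits cannot show how far the calls depend on either.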

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

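The results below are differences of the ppx effect between cell classes, given as values, and 3 patterns weighed against technical explanations. The test in wells low in immediate early transcripts was chosen before its result was seen. The other tests of this part, with the counts over other splits of the plates, were chosen after the results they measure were seen.

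Interaction tests in edgeR set the ppx effect in beta-like wells against that in another class, with plate as a block (n = 3 plates per operation, with 7 and 4 delta-like wells on ppx replicates 2 and 3). Against delta-like wells the difference was 3.25 ± 0.57 on the log2 scale for Gc (adjusted p = 6.2e-05) and 5.38 ± 1.08 for Cela1 (adjusted p = 0.0013). Of the 424 Cela1 UMIs in beta-like wells of ppx replicate 3, 415 lay in a single well with 60.1% of its UMIs in acinar markers. Against alpha-like wells the difference was -6.01 ± 0.84 for Mpp3 (345 UMIs in alpha-like wells of ppx replicate 2), 1.24 ± 0.21 for Ttr, 1.11 ± 0.21 for Gc, -1.13 ± 0.23 for Hist1h2bc, 1.10 ± 0.23 for Rnase4, 2.64 ± 0.61 for Olfm1 and -1.10 ± 0.26 for Adgrg1. For Ghrl it was -4.74 ± 0.79, with 2045 UMIs in a single alpha-like well of ppx replicate 1, and 0.22 without that plate.

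The 10 splits of 6 plates into 3 and 3 are too few for a share under 0.05. The real split gave 2 genes against delta-like wells and the highest other 3 (3 of 10 splits gave as many), and 8 genes against alpha-like wells with the highest other at 4 (1 of 10). In somatostatin-only wells it gave 1 gene and the highest other 2 (3 of 10), and for the lists in beta-like wells 6 lists and the highest other 8 (3 of 10). For joined wells against in silico pairs, 8 of 32 swaps of labels within plates gave as many as the 1 gene found, the highest other being 3, so chance is not excluded there.

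The first pattern weighed is the rise of endoplasmic reticulum chaperone genes in beta-like wells of ppx plates. A few genes taking most of the counts are argued against, since 8 of the 8 called members still rose with the hormone genes left out. The tomato-positive plates, which have few beta-like wells, are argued against as the source, since 8 members also rose without both. A rise confined to wells with a larger immediate early share is argued against. Handling of the islets itself stays open, since it can act on every well of a plate, including those low in immediate early transcripts. In wells low in immediate early transcripts the list median was 0.56, with 4 of the 8 members still called on fewer wells and plates. The tomato-positive plates had 7 and 9 such wells and were left out there. All beta-like wells gave a median of 0.51 without these plates and 0.43 with them. Handling that acts without an immediate early response was not tested. The real split gave 49 genes and the highest other 19 (1 of 10, too few splits for a share under 0.05). In alpha-like wells the list was also higher as a set (17 of 18 members positive, camera adjusted p = 0.041 with an estimated correlation). No member was called in the direct test of beta-like against alpha-like wells, so the rise is not shown to be particular to beta cells. A response of beta cells to the operation may remain as a hypothesis. The pancreas behind each plate and the day of its preparation are not in the labels and stay open.

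The second pattern is higher Ppy and Pyy with lower Gfra3 in alpha-like wells of ppx plates. Another mix of glucagon-high and glucagon-low wells stays open: in glucagon-high wells the median change of the 15 genes was 0.87 in the called direction against 1.30 in all wells of the class, but the genes were picked in a class that holds those same wells. None of them passed in edgeR there (0 genes called, 131 at an unadjusted p under 0.05, no other tool run), with fewer wells and larger errors, and Ppy went from 1.71 ± 0.29 to 1.39 ± 0.37. The part of the pancreas the islets came from cannot be told apart from the operation, which removes part of the pancreas. Wells dominated by Ppy were more frequent by 2.62 points on ppx plates (exact permutation p = 0.1, n = 3 each), which decides nothing alone. The real split gave 15 genes with the highest other at 8 (1 of 10, too few for a share under 0.05).

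The third pattern is that insulin-high wells of the tomato-positive plates are also somatostatin-high far more often than those of the negative plates, at 70% and 79.4%, or 31.7% and 30.2% with thresholds at 0.25 of the class median. Free somatostatin RNA in wells of single beta cells stays open: such wells held 1.24-fold the median UMIs of insulin-only wells over 6 of 6 plates (exact p = 0.031), but the log2 ratio was 0.13 and 0.58 on the tomato-positive plates, too few for a test of their own. Random joining of cells stays open, with a log2 ratio of beta-delta to beta-alpha wells of 2.59 over 6 plates (exact p = 0.0625, above 0 on 5 of 6), and of 1.55 and -0.16 on the tomato-positive plates. A sort gate that takes any cell joined to a marked delta cell is consistent with the glucagon-high wells not high in insulin, which were also somatostatin-high more often on positive plates by 46.6 points (exact permutation p = 0.1, n = 2 and 3). Single cells that make both hormones, and lineage marking of the beta cell in such wells, were not tested.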

How the results depend on the processing

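The glucagon-high wells, the wells low in immediate early or acinar transcripts, the comparison in somatostatin-only wells, and the lists without tomato-positive plates were chosen after the data were seen. Over the alternatives, 112 values of the main results were labelled the same, 32 weaker, 13 stronger and 12 reversed. For shares, enrichment and single genes, the same means direction and side of the threshold kept. For numbers of genes or lists called, it means a number close to the main one, whichever genes or lists were called. For 71 named called genes, 830 of 1136 values were the same, 305 weaker and 1 reversed. Where no reason is given, the cause was not tested.

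The difference in the share of insulin-high and somatostatin-high wells (0.0295 points, exact permutation p = 1) changed sign with at least 1000 UMIs (-0.0369), without the mitochondrial filter (-0.128), at Leiden resolution 0.5 (-0.159), with thresholds at 0.25 (-1.36) or 0.1 (-0.160) of the class median, and without tomato-positive plates (-2.88). Leaving out 1 plate gave -6.67 to 3.81 points, and -19.4 to 10.3 for delta-like wells, the extremes being the tomato-positive plates. The enrichment of beta-delta over beta-alpha wells was 2.78 (exact p = 0.031) with thresholds at 0.1. It was 2.34 with thresholds at 0.25 (exact sign-flip p = 0.125) and 2.68 with at least 1000 UMIs (exact sign-flip p = 0.0625). Leaving out 1 plate gave 2.19 to 3.13.

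In beta-like wells edgeR called 49 genes, DESeq2 13, edgeR without the count filter 102, and 10 in wells low in immediate early transcripts. Leaving out 1 plate gave 21 to 50. In alpha-like wells 15 genes became 29 without the filter, 0 in glucagon-high wells (131 at an unadjusted p under 0.05), and 6 to 26 without 1 plate. In somatostatin-only wells 1 gene became 3 without the filter, 4 with replicate number as a block, 3 with tomato status as a covariate, 8 without tomato-positive plates, and 1 to 9 without 1 plate. The difference between beta-like and delta-like wells gave 0 genes without the filter and 0 to 3 without 1 plate, that between beta-like and alpha-like wells 4 to 12. In silico pairs gave 2 genes without the filter, 0 in draws 2, 4 and 5, 0 with thresholds at 0.25, and 0 to 1 without 1 plate. The tomato comparison called 15 genes, 3 by DESeq2, 3 without the filter, 4 without the covariate, and 5 to 10 without 1 negative plate. Without a positive plate a single one is left, so no count is given. Of 6 gene lists in beta-like wells, 0 passed with an estimated correlation and 1 with fry.

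Hormone genes past no threshold in the main setting changed sign in places. Sst in beta-like wells (1.04) was -0.38 without tomato-positive plates and -0.71 to 1.70 without 1 plate. Without doublets it was -0.98 and passed (edgeR adjusted p = 0.0273), but that setting selects wells on Sst itself. Ins2 in beta-like wells ranged from -1.80 to 0.14 without 1 plate. In alpha-like wells Ins1 was 0.14 without tomato-positive plates, 0.13 with at least 1000 UMIs and 0.097 without doublets (-0.63 to 0.11 without 1 plate). Ins2 was 0.059 with at least 1000 UMIs and 0.36 in glucagon-high wells (-1.29 to 0.31). Sst was 1.73 without doublets (-0.60 to 0.014) and Gcg 0.25 in glucagon-high wells. Both settings select wells on the hormones themselves, so these values are no test of them. The Ghrl difference between beta-like and alpha-like wells ranged from -5.00 to 0.22 without 1 plate, the latter without ppx replicate 1, whose single well holds most Ghrl UMIs of the class.

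Fold changes within a replicate number correlated with r = 0.020, 0.026 and 0.008 in beta-like wells. Such values cannot decide whether the numbers pair the plates. Replicate 1 was tomato-positive in both operations, so that the number partly follows the tomato sort. With the number as a block, Ins2 in beta-like wells went from -0.33 (edgeR adjusted p = 0.79) to -1.03 (adjusted p = 2.8e-13). Ins1 passed in neither setting (adjusted p = 0.635 and 0.624). The blocked p-value of Ins2 does not reflect the spread between replicates. From sham to ppx, Ins2 went from 11.8% to 19.2% of UMIs in replicate 1. It went from 12.2% to 4.73% in replicate 2 and from 10.5% to 2.20% in replicate 3. With the number as a block, 61 genes passed in beta-like and 20 in alpha-like wells, and the p of the beta-like share was 0.5. Not run, for too few plates with 10 wells, were alpha-like wells at resolution 2 and delta-like wells at resolution 1 with their other alternatives. The tomato comparison without sham replicate 2 is the comparison itself.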

Other observations

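The values of this part were looked at after the data were seen. Ghrl, which encodes ghrelin, had 1741 UMIs on the tomato-positive sham plate and 5276 on the tomato-positive ppx plate, in 29.6% and 62.4% of wells, and 0 on the other 4 plates, where limits are 0.829% to 0.885% of wells. Of the 1741 UMIs, 1606 lay in 1 well, and of the 5276, 2 wells held 2788 and 2045.

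Wells with at least 10% of UMIs in Ppy made up 3.66%, 2.83% and 4.13% of the sham plates and 5.90%, 7.73% and 4.86% of the ppx plates (exact permutation p = 0.1, n = 3 each). E130111B04Rik lies 64.8 kb from Ppy on chromosome 11, 1.81 kb from Mpp3, and Ppy 5.36 kb from Pyy. In beta-like wells E130111B04Rik, named here after its value was seen, rose by 2.3 ± 0.48 in edgeR (adjusted p = 0.0049), with plates that overlap: 0, 6.19 and 14 CPM on the sham plates and 0, 124 and 17.1 CPM on the ppx plates, so that the rise rests on ppx replicate 2. In wells with at least 10% of UMIs in Ppy, its mean on the log2 scale was higher by 1.85 on ppx plates (exact permutation p = 0.2, n = 3 each, plates overlapping) and differed by -2.34 between tomato-positive and tomato-negative plates (exact permutation p = 0.1, n = 2 and 3).

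Sox9 had 60 UMIs in 41 wells. Of delta-like wells 4.84% had at least 1 (median depth 1664 UMIs), of beta-like wells 0.103% (4247.5 UMIs) and of the cluster with endothelial and stromal markers 8.51% (886 UMIs). Of the 41 wells, 13 and 19 lay on the tomato-positive sham and ppx plates, which held 169 and 180 of the 413 delta-like wells. On these plates 0 of 19 and 0 of 16 beta-like wells had a UMI, with limits of 15.8% and 18.8%. In the cluster, 4 of 8 and 3 of 12 wells of these plates had one. At Leiden resolution 2 the endothelial cluster had 0 wells on either of these plates. The cluster with stromal and duct markers, Spp1 and Clu among them, had 8 and 12. The Sox9 counts of these plates are thus not shown to come from endothelial cells. Class and plate cannot be told apart here.

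The mean log2 ratio of Ins2 to Ins1 in beta-like wells was -0.36, 0.26 and -0.47 on the sham plates and 0.69, -1.18 and -2.47 on the ppx plates (difference -0.79, exact permutation p = 0.5, n = 3 each). In wells high in insulin and somatostatin it was -0.14, 0.35 and -0.60, and 0.82, -0.86 and -2.47. A doublet score (Scrublet) marked 14 of the 175 such wells, 8.0%, and 82 of all 2115 wells, 3.88%.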
